A study of Homo sapiens with 18 samples.

How the data were processed

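Total RNA of HEK293 cells, a line derived from human embryonic kidney, was sequenced; how messenger RNA was selected is not stated. Per the labels, cells were transfected with X-tremeGENE HP and harvested 24 to 48 h later, RNA was extracted with Trizol and libraries were made with a NEBNext Ultra II RNA kit. The deposited table holds counts: raw, whole-number reads per gene for 18 libraries, 1 column per library, with no normalization by the authors. Per the submitters' processing notes, reads were checked with FastQC, aligned to GRCh38/hg38 with STAR and assigned to genes with featureCounts, and DESeq2 was used for testing. Their versions, the annotation release, the strand setting and any filter were not given. The table has 39284 genes, of which 9652 have no read in any library. In units of 1e6 counts, library totals ran from 10.0 to 24.4, so that 3 counts are between 0.123 and 0.299 CPM (counts per 1e6 counts). Floors of this kind cover counting error only, since the reads carry no molecular identifiers.

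The labels place the libraries in 7 groups: untransfected (2), empty vector (3), TMEM213 (2), TMEM207 (3), TMEM116 (3), TMEM72 (2) and TMEM30B (3). The series design states 3 biological replicates per TMEM gene; the table holds 2 for TMEM213 and for TMEM72, and the absent ones were not analysed here. The labels give each library a number between 1 and 30. Those numbers were not used in the planned comparisons and served as a block in alternatives. Replicates are those of the series design, and the p-values measure the spread between its samples.

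Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0; tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes were filtered with filterByExpr by group, which left 16726 genes (16642 when only the 16 transfected libraries were used), and counts were scaled by TMM. Each comparison was an edgeR quasi-likelihood test with robust dispersion on group means, all 18 libraries in 1 fit, and p-values were adjusted by Benjamini-Hochberg; the threshold was an adjusted p of 0.05 with no fold limit. The 6 main comparisons set each TMEM group against empty vector, and empty vector against untransfected. A further 5 set each TMEM group against the mean of the other 4, and 1 F test asked for any difference among the 6 transfected groups. Gene lists, 30 in all and written before the data were examined, were tested with limma camera on log CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 29 lists that had at least 3 tested genes. Camera was also run with an estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone. Fold changes are on the log2 scale with their standard error (SE); levels are CPM, as mean ± SD.

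The rule for named genes was fixed before the data were examined: the transfected genes; of other genes past the threshold with a mean of at least 5 CPM in 1 group and no overlap between groups, up to 8 rises and 8 falls per main comparison; of each list, up to 3 members past the threshold; and where fewer than 5 genes qualified, the 5 with the smallest p, given as values. For that last part the genes were taken other than the inserts. No gene other than the inserts qualified by the threshold in any main comparison, so these 5 per comparison are the planned genes, and every other gene named below was chosen after its values were seen. Positions come from GENCODE v29 on GRCh38, in which 39238 of the 39284 gene identifiers were found, and 16718 of the 16726 tested.

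Alternatives fixed before the data were examined were RLE scaling, DESeq2, limma voom with sample quality weights, no low-count filter, a mean of at least 10 reads, a stricter threshold of 0.01, a log2 fold limit of 1, the replicate number as a block, the library number as a block in ranges 1 to 10, 11 to 20 and 21 to 30, only the groups of the comparison, the tests without the 5 TMEM genes, untransfected cells as the control, and leaving out each library. The replicate block of the labels gave 730 genes for TMEM72 against empty vector and 6853 for empty vector against untransfected, and its numbers were checked as pairs by correlating each library's log CPM, centred on its group's mean, across genes with the empty-vector library of its number. TMEM207, TMEM116 and TMEM30B libraries correlated with it at 0.671 to 0.927. TMEM213 replicates 1 and 2 gave 0.651 and -0.777, TMEM72 replicates 0.592 and -0.78, and untransfected replicates -0.339 and -0.146, so replicate numbers do not pair the libraries in those groups and the replicate block mixes library sets there. After the data were seen, a block of 3 library-number ranges (1 to 10, 11 to 19 and 20 to 30, with library 20 moved) was added, since library 20 had the expression profile of libraries 21 to 30; it is called the range fit below. Also added then were a block of the sets 1 to 19 and 20 to 30, the range fit with DESeq2 and with limma voom, the range fit leaving out each library, and libraries 1 to 19 alone.

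The common biological coefficient of variation was 0.429 in the planned fit (11 residual degrees of freedom) and 0.108 in the range fit (9 residual degrees of freedom). Both were tested on simulated data with this design, with 200 changed genes of 16601 in each comparison. The means and dispersions of the simulation came from the range fit itself, and the changed genes were drawn from those with higher counts. The simulation therefore favours the range fit, and the shares recovered may be lower in the real data. The planned fit recovered 14 to 26% of 2-fold changes and 52 to 69% of 4-fold changes, with 0 false calls. The range fit recovered 81 to 90% and 98 to 100%, with 10 to 15 false calls. Other splits and shuffled labels were also run, as were tests of technical explanations. The 5 TMEM comparisons share the same empty-vector libraries.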

Results

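RNA was sequenced from HEK293 cells that overexpressed 1 of 5 transmembrane protein genes (TMEM213, TMEM207, TMEM116, TMEM72 or TMEM30B), from cells that received the empty vector and from untransfected cells. The 18 libraries fall into 7 groups. Empty vector, TMEM207, TMEM116 and TMEM30B have 3 libraries each, and untransfected, TMEM213 and TMEM72 have 2 each. In units of 1e6 counts, the shallowest library, TMEM207 replicate 2, holds 10.03 and the deepest, untransfected replicate 1, holds 24.36. The empty-vector libraries hold 13.33, 18.39 and 23.52, the TMEM213 libraries 15.9 and 15.94, and untransfected replicate 2 holds 20.87. The other TMEM207 libraries hold 12.26 and 19.3, the TMEM116 libraries 15.08, 16.67 and 20.73, the TMEM72 libraries 13.28 and 15.19, and the TMEM30B libraries 14.88, 15.38 and 16.73.

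Each transfected gene was strongly overexpressed in the libraries labelled with it. TMEM72 reached 22510 ± 16680 CPM (SD, n = 2) in its own libraries, against 2.276 ± 2.937 CPM (n = 3) with the empty vector. TMEM30B, a subunit of phospholipid flippases, reached 11080 ± 1499 CPM (n = 3) against 1.621 ± 0.2343 CPM. TMEM207 stood at 4285 ± 3787 CPM (n = 3) against 0.7645 ± 0.6983 CPM, and TMEM213 at 4141 ± 3692 CPM (n = 2) against 0.9006 ± 1.05 CPM. TMEM116, the insert with the highest level of the 5 in vector and untransfected cells, stood at 1815 ± 570.8 CPM (n = 3) against 15.87 ± 3.289 CPM with the vector and 24.41 ± 4.506 CPM (n = 2) in untransfected cells. Against the vector library of the same library-number range, the inserts were 2810 and 3240 times higher for TMEM213 and 79.4 to 185 times higher for TMEM116. They were 6110 and 9380 times higher for TMEM72 and 6520 to 7200 times higher for TMEM30B. For TMEM207 the folds were 5330 and 6880 and, in replicate 2, where the vector library holds 3 counts, 3560 (95% counting interval 1220 to 17200). The few TMEM213, TMEM207 and TMEM72 reads of the vector libraries may be stray reads, as described further below. The folds of these 3 inserts may then be too low. Levels of 1 insert varied between its libraries: TMEM207 ran from 580 to 8150 CPM and TMEM213 from 1530 to 6752 CPM. TMEM30B stood at 1.108 to 2.962 CPM in the libraries that did not receive it other than TMEM213 replicate 1; whether these are the cells' own transcripts was not tested. It was present at 1236 CPM in TMEM213 replicate 1, against 1.882 CPM in TMEM213 replicate 2.

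**Figure D1:**
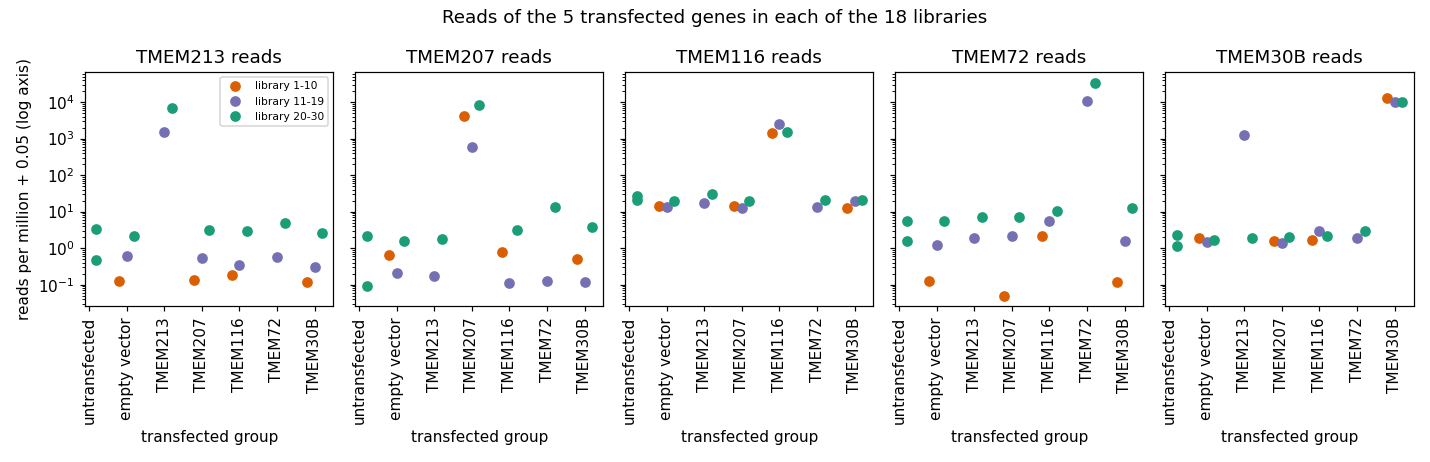
Reads per (with 0.05 added, log axis) of the 5 transfected genes in the 18 libraries, 1 point per library, by transfected group and coloured by library-number range. Each gene is highest in its own libraries, and TMEM30B also stands at 1236 CPM in TMEM213 replicate 1.

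The largest difference between libraries followed their numbers, not the transfected gene. Libraries 20 to 30 expressed almost no KRT19, a keratin of simple epithelia, which stood at 0.0219 ± 0.0448 CPM (n = 8) against 131 ± 20.8 CPM (n = 10) in libraries 1 to 19. PEG10, an imprinted retrotransposon-derived gene, stood at 2.01 ± 0.37 against 394 ± 73.2 CPM. HSPA1A, an inducible Hsp70 chaperone, stood at 426 ± 208 CPM in libraries 20 to 30 against 0.336 ± 0.27 CPM. Its paralog HSPA1B can share reads with it. In the vector libraries HSPA1B was at 542, 474 and 256 CPM where HSPA1A was at 0.225, 0.218 and 279 CPM. In the TMEM72 libraries HSPA1B was at 523 and 768 CPM. Whether the sets differ in the sum of both genes was not tested. The Notch target HES5 stood at 42.2 ± 14.9 CPM against 0.0335 ± 0.083 CPM. Of 50 genes of cytosolic ribosomal proteins, 47 were lower in libraries 20 to 30, among them RPS16 (699 against 3270 CPM) and RPS19 (854 against 3050 CPM), and 0 were higher. The 1st principal component, 74.8% of the variance, separated 10 libraries numbered 1 to 19 from 8 numbered 20 to 30. Across genes, which are not independent replicates, Spearman's rho was 0.97 to 0.996 within the first set, 0.978 to 0.997 within the second and 0.905 to 0.944 between them. Within the 16 transfected libraries, where the division falls between library 19 and library 21, 70% of 16642 genes differed by an edgeR quasi-likelihood test with the group as a term. In the higher numbers 5863 were higher and 5786 lower. Every transfected group has libraries in both sets, whereas both untransfected libraries are in the second. The balance differs, though: empty vector has 2 libraries in the first set and 1 in the second, while TMEM213 and TMEM72 have 1 in each. The planned fit has no block, so for TMEM213 and TMEM72 against empty vector it mixes the insert with the difference between the sets.

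**Figure D2:**
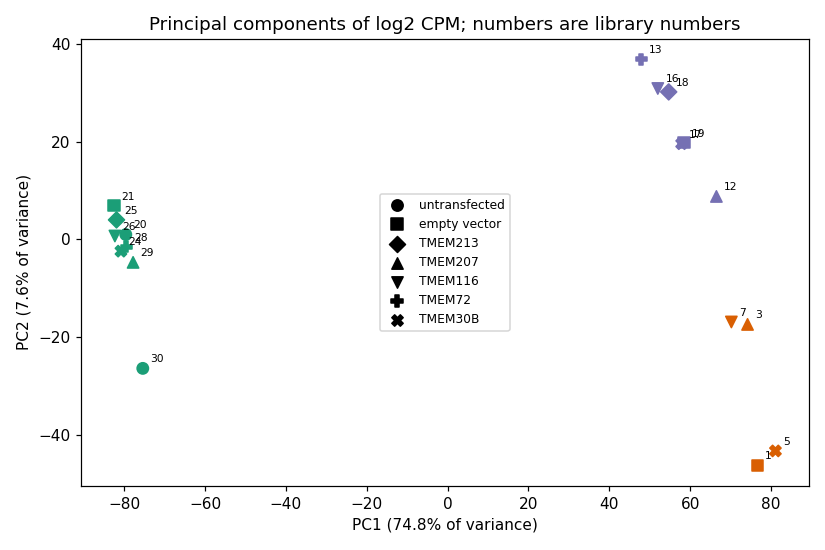
Principal components of log2 CPM for the 18 libraries, with the share of variance on each axis; shapes are groups, colours are library-number ranges and the numbers are library numbers. Libraries 1 to 19 lie on the right and libraries 20 to 30 on the left along a component with 74.8% of the variance.

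The comparison of TMEM213 against empty vector asks what the insert changes beyond transfection itself. TMEM213 (chromosome 7, 138797952 to 138838101) was 12 log2 units higher (SE 1.81, adjusted p = 0.22). In the range fit it was 11.7 higher (SE 0.48, adjusted p = 8.98e-10, higher in 2 of 2 libraries). Over its alternatives the adjusted p ran from 2.17e-43 to 1. By smallest p, the other genes were APOA1, the main protein of high-density lipoprotein (log2 fold change -2.5, SE 0.75), SHBG, a carrier of sex steroids (-1.82, SE 0.64), and SAPCD1 (1.21, SE 0.44). The pseudogenes DGKZP1 (2.12, SE 0.77) and MCFD2P1 (-2.1, SE 0.77) followed. Each of the 5 had an adjusted p of 1, and they were at 3.14 CPM or less in these libraries. APOA1 was at 0.0629 and 0.188 CPM with TMEM213 and at 0.9, 0.707 and 0.425 CPM with the vector. All 50 ribosomal protein genes had negative values (median -0.665, adjusted p = 2.72e-11 by camera), with RPS28 at -0.84. So did 34 of 36 nuclear genes of oxidative phosphorylation (median -0.313, adjusted p = 9e-08), with NDUFA1 at -0.56. In the same direction were cholesterol synthesis (19 of 24 negative, adjusted p = 0.0242), hypoxia and glycolysis (25 of 32, adjusted p = 0.0117) and immediate early genes (20 of 24, adjusted p = 0.0117). Negative too were integrated stress response genes such as DDIT3 (18 of 30, adjusted p = 0.0348), NF-kB targets (15 of 18, adjusted p = 0.0348) and S phase genes such as PCNA (22 of 30, adjusted p = 0.0117). Mitochondrial-encoded transcripts were positive for 12 of 15 (adjusted p = 0.0348). With an estimated correlation the adjusted p was 0.689 for immediate early genes and 0.665 for the other 8 lists. In these lists 0 members passed the threshold, over all genes or adjusted over the list alone. Matched to the vector library of the same range, the ribosomal genes were lower in replicate 1 (6 of 50 higher, median -0.0576) and higher in replicate 2 (37 of 50 higher, median 0.0413). Of the oxidative phosphorylation genes, 18 of 36 were higher in each replicate (medians 0.00933 and -0.0048). Integrated stress response genes were lower in replicate 1 (2 of 30 higher, median -0.0912) and mostly higher in replicate 2 (19 of 30, median 0.0384). S phase genes were mostly lower in both (6 and 10 of 30 higher). The range fit did not call 5 of the 9 lists: cholesterol synthesis (adjusted p = 0.315), hypoxia (0.143), immediate early genes (0.421), NF-kB targets (0.143) and mitochondrial-encoded transcripts (0.143). In that fit the medians were smaller, for example -0.0591 against -0.339 for immediate early genes, -0.149 against -0.607 for NF-kB targets and -0.182 against -0.665 for ribosomal proteins. TMEM213 and TMEM72 have no library in range 1 to 10. There the ribosomal medians against empty-vector replicate 1 were -0.627 for TMEM207, -0.585 for TMEM116 and -0.359 for TMEM30B. The range fit also uses that vector library, so its ribosomal values for TMEM213 and TMEM72 cannot be read as effects of the insert. No gene passed the threshold with edgeR (0 genes, 35 at an unadjusted p under 0.05), against 2 with DESeq2 (TMEM213 and TMEM30B), 1 with limma voom and 1 in the range fit, the insert itself. The 35 are far below a 0.05 share of the 16726 genes tested, so they are no sign of further changes.

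In the comparison of TMEM207 against empty vector, the mitochondrial-encoded transcripts were the group with the smallest p. Of 15, 13 had positive values (median 0.253, adjusted p = 1.6e-05 by camera, 0.961 with an estimated correlation). This list was written as a sign of RNA quality. In ranges 1 to 10, 11 to 19 and 20 to 30, 12, 14 and 14 were higher in the TMEM207 library than in the vector library of its range. MT-CYB, a subunit of respiratory complex III, had a log2 fold change of 0.28 and, in the range fit, of 0.37 (SE 0.14, adjusted p = 0.869). It had -0.05 without empty-vector replicate 1 and -0.2 without TMEM207 replicate 3. EGR1, an immediate early transcription factor, stood at 23.8, 12.9 and 9.95 CPM against 10.3, 8.48 and 4.63 CPM with the vector, ordered by range. Its log2 fold change was 0.98 in the range fit (SE 0.23, adjusted p = 0.869). Nuclear genes of oxidative phosphorylation had negative values in 34 of 36 (median -0.205, adjusted p = 0.00571), with NDUFA2 at -0.38 (0.13 without empty-vector replicate 1). They were lower than in the vector library in range 1 to 10 (2 of 36 genes higher), but 32 and 27 of 36 were higher in the other ranges. With an estimated correlation the adjusted p was 0.961 for both lists, and 0 members of either passed the threshold, over all genes or adjusted over the list alone. TMEM207 itself (chromosome 3, 190428655 to 190449876) was 12.39 log2 units higher (SE 2.16, adjusted p = 0.998). It was 12.61 higher in the range fit (SE 0.54, adjusted p = 1.46e-09, higher in 3 of 3 libraries). Over its alternatives the adjusted p ran from 4.05e-29 to 1. The other genes with the smallest p were the read-through gene BCL2L2-PABPN1 (1.91, SE 0.44), LINC01869 (-1.73, SE 0.48), JARID2-AS1 (1.57, SE 0.47), RPS27AP11 (-3.59, SE 1.13) and the carbohydrate kinase gene FGGY (-1.15, SE 0.36), each with an adjusted p of 1. FGGY stood at 2.2, 1.2 and 3.68 CPM against 4.13, 4.62 and 7.06 CPM. With edgeR 0 genes passed (59 at an unadjusted p under 0.05), with DESeq2 1 and in the range fit 1, both the insert, and with limma voom 0.

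In TMEM116 against empty vector, hypoxia and glycolysis genes had mostly negative values, 29 of 32 (median -0.242, adjusted p = 4.9e-08 by camera). P4HA1, a collagen prolyl hydroxylase subunit, stood at 82.4 ± 5.32 CPM (n = 3) against 124 ± 33.9 CPM (n = 3; log2 fold change -0.64, SE 0.26, adjusted p = 1). The mitophagy receptor gene BNIP3L stood at 88.8 ± 8.2 against 111 ± 16.7 CPM (-0.36, SE 0.14, adjusted p = 1). Within ranges 1 to 10, 11 to 19 and 20 to 30, the median of the list was -0.302, -0.312 and -0.0375. Mitochondrial-encoded transcripts were positive in 13 of 15 (median 0.266, adjusted p = 3.74e-06), with within-range medians of 0.18, 0.318 and 0.262 and MT-CYB at 0.45 (-0.03 without TMEM116 replicate 3). All 50 ribosomal protein genes (median -0.333, adjusted p = 0.000425; RPSA -0.43) and 35 of 36 nuclear oxidative phosphorylation genes (median -0.215, adjusted p = 2.88e-05; NDUFA2 -0.41) had negative values. In range 20 to 30, though, 49 of 50 and 30 of 36 were higher. Smaller negative medians were found for endoplasmic reticulum (ER) chaperones (18 of 21, adjusted p = 0.00816; HSPA5 -0.34) and S phase genes (27 of 30, adjusted p = 0.00816; GINS2 -0.26). These also turned in range 20 to 30, where 15 of 21 (median 0.0546) and 19 of 30 (median 0.0346) were higher. Negative medians were also found for ER-to-Golgi transport (34 of 39, adjusted p = 0.00597; SSR3 -0.29) and cholesterol synthesis (18 of 24, adjusted p = 0.0334; IDI1 -0.36). Without empty-vector replicate 1, RPSA had 0.06, NDUFA2 0.1 and HSPA5 0.01. With an estimated correlation the adjusted p was 0.301 for hypoxia, mitochondrial-encoded transcripts and ER-to-Golgi transport, 0.662 for ribosomal proteins and 0.515 for the other 4 lists. In these lists 0 members passed the threshold, over all genes or adjusted over the list alone. Replication-dependent histones, a sign of RNA selection, were negative in 15 of 18 (median -0.536), and fibroblast markers were positive in 5 of 7 (median 0.228). The planned fit called neither list. The range fit called both by camera (adjusted p = 8.77e-06 and 0.00677, 0.19 and 0.235 with an estimated correlation). TMEM116 (chromosome 12, 111931282 to 112013185) was the 1 gene past the threshold (log2 fold change 6.81, SE 0.34, adjusted p = 2.89e-07, higher in 3 of 3 libraries). The other genes with the smallest p were HDHD5-AS1 (-1.37, SE 0.39), HNRNPD-DT (-1.16, SE 0.37), SAPCD1 (1.17, SE 0.4), LINC01869 (-1.36, SE 0.47) and TTYH3 (0.34, SE 0.13), each with an adjusted p of 1.

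In the comparison of TMEM72 against empty vector, inducible heat shock genes stood out. HSPA6, a strictly inducible Hsp70, was at 2.18 and 19.5 CPM with TMEM72 and at 0.6, 0.272 and 0.213 CPM with the vector (log2 fold change 4.78, SE 0.99, adjusted p = 1). It passed the threshold in the range fit (4.86, SE 0.76, adjusted p = 0.0422, higher in 2 of 2 libraries) and with DESeq2. Over its alternatives the adjusted p ran from 0.00136 to 1. HSPA1A stood at 907 CPM in TMEM72 replicate 2 against 279 CPM in the vector library of its range. In range 11 to 19, where few reads were assigned to it, it stood at 0.603 against 0.218 CPM. In the range fit it rose by 1.71 log2 units (SE 0.21, adjusted p = 0.00155, from 0.000116 to 1 over its alternatives). The planned fit gave HSPA1A 2.36 (SE 3.48, adjusted p = 1), -7.1 without TMEM72 replicate 2 and 10.77 without empty-vector replicate 3. DNAJB1, the Hsp40 partner of these chaperones, was at 106 and 251 CPM against 125, 93.3 and 80.9 CPM. HSPA1B, a paralog of HSPA1A, with which it can share reads, was at 523 and 768 CPM against 542, 474 and 256 CPM. Of 20 heat shock genes, 16 had positive values (median 0.174, adjusted p = 0.0146 by camera, and 0.536 with an estimated correlation). Of these genes 1 passed adjusted over the list alone and 0 over all genes. The list was higher mainly in replicate 2, with 19 of 20 genes above the vector library of its range (median 0.283), against 11 of 20 in replicate 1 (median 0.0347). The range-fit calls of both HSPA6 and HSPA1A were lost without TMEM72 replicate 2 and without empty-vector replicate 3, and that of HSPA6 also without either other vector library. Limma voom with the ranges called neither.

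**Figure D3:**
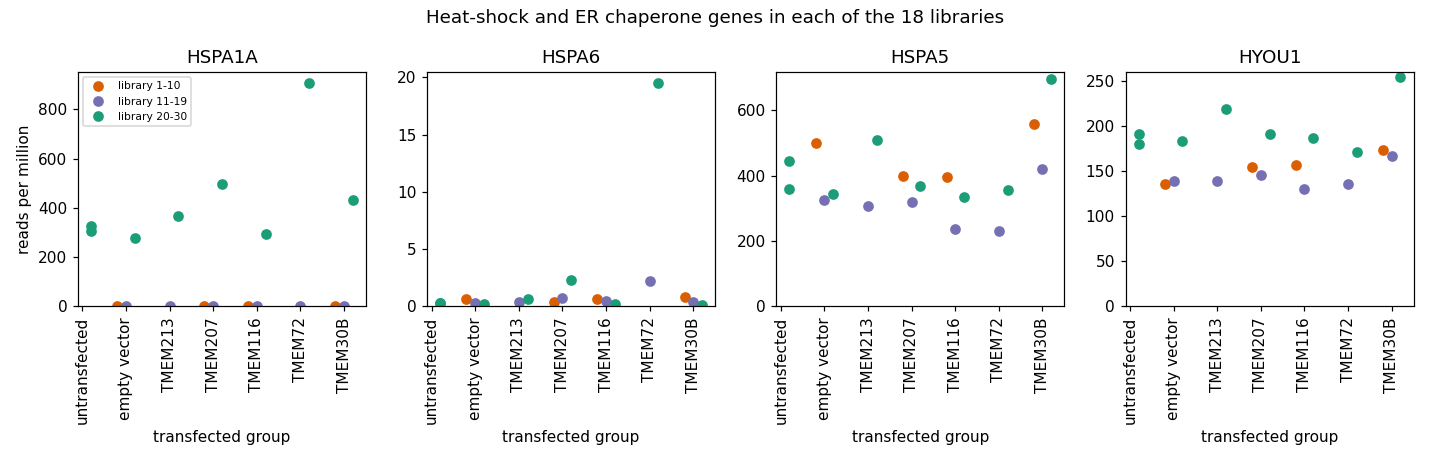
Reads per of the heat shock genes HSPA1A and HSPA6 and of the ER chaperone genes HSPA5 and HYOU1 in the 18 libraries, 1 point per library, by transfected group and coloured by library-number range. HSPA1A reaches 907 CPM and HSPA6 19.5 CPM in TMEM72 replicate 2, and HSPA5 reaches 695 CPM in TMEM30B replicate 3.

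Other groups in the comparison of TMEM72 against empty vector had negative values: all 50 ribosomal protein genes (median -0.656, adjusted p = 5.1e-09; RPL6 -0.53), 17 of 21 ER chaperones (adjusted p = 0.00513; HSPA5 -0.53) and 29 of 39 ER-to-Golgi genes (adjusted p = 0.0181; SSR3 -0.38). So did 22 of 30 G2 and mitosis genes (adjusted p = 0.00566; CDK1 -0.51), 22 of 32 hypoxia genes (adjusted p = 0.00566; P4HA1 -0.56) and 31 of 36 nuclear oxidative phosphorylation genes (adjusted p = 0.000476). Integrated stress response genes were negative for 19 of 30 (adjusted p = 0.0266), among them the asparagine synthetase gene ASNS (-1.01, SE 0.59). Mitochondrial-encoded transcripts were positive in 13 of 15 (median 0.265, adjusted p = 8.26e-05; MT-CYB 0.7). With an estimated correlation the adjusted p was 0.536 for each of these lists. Beyond heat shock, 0 members passed the threshold, over all genes or adjusted over the list alone. Against the vector library of the same range, nuclear oxidative phosphorylation genes were not lower in either TMEM72 library (21 of 36 higher, median 0.0218, and 30 of 36 higher, median 0.138), and in the range fit the list was not called (adjusted p = 0.102). Several lists were lower in replicate 1 and higher in replicate 2: ribosomal proteins (1 and 48 of 50 higher), hypoxia (3 and 26 of 32), ER chaperones (3 and 13 of 21) and the integrated stress response (6 and 19 of 30). G2 and mitosis genes (8 and 5 of 30 higher) and ER-to-Golgi genes (8 and 18 of 39) were lower in both. TMEM72 (chromosome 10, 44911200 to 44937002) was 13.24 log2 units higher (SE 2.08, adjusted p = 0.339). With the ranges as a block it was 12.87 higher (SE 0.6, adjusted p = 6.68e-09, higher in 2 of 2 libraries). Over its alternatives the adjusted p ran from 1.47e-32 to 1. Besides HSPA6, the genes with the smallest p were ADPGK-AS1 (-2.51, SE 0.68), MIR3659HG (-2.03, SE 0.66), SAPCD1 (1.33, SE 0.44) and LUCAT1 (-1.62, SE 0.57), each with an adjusted p of 1. With edgeR 0 genes passed (54 at an unadjusted p under 0.05), with DESeq2 1, with limma voom 1, and in the range fit 3.

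In the comparison of TMEM30B against empty vector, ER chaperone genes had higher values: 19 of 21 were positive (median 0.112, adjusted p = 9.25e-05 by camera). HSPA5, the ER Hsp70 known as BiP, stood at 558 ± 136 CPM (n = 3) against 390 ± 94.8 CPM (n = 3; log2 fold change 0.5, SE 0.3, adjusted p = 1). HYOU1, another ER chaperone of the Hsp70 family, stood at 198 ± 48.4 against 153 ± 26.1 CPM (0.4, SE 0.17, adjusted p = 1). The disulfide isomerase PDIA4 stood at 353 ± 192 against 266 ± 63.4 CPM (0.4, SE 0.31, adjusted p = 1). HSPA5 and HYOU1 were each above the vector library in all 3 ranges, and HYOU1 passed the threshold with DESeq2 and the ranges (adjusted p = 0.0199, the lowest of its alternatives, of which the highest was 1). The list was at -0.036, 0.0824 and 0.315 within ranges 1 to 10, 11 to 19 and 20 to 30, with 8, 17 and 21 of 21 genes higher. PDIA4 had -0.01 without TMEM30B replicate 3. Mitochondrial-encoded transcripts were positive in 13 of 15 (median 0.161, adjusted p = 0.00426; MT-ND4L 0.26). With an estimated correlation the adjusted p was 0.831 for ER chaperones and 0.989 for mitochondrial-encoded transcripts. In both lists 0 members passed the threshold, over all genes or adjusted over the list alone. Phospholipid flippases and scramblases, the family with which TMEM30B works, had positive values in 12 of 19 (median 0.0499, adjusted p = 0.94). TMEM30B (chromosome 14, 61277370 to 61281840) was 12.78 log2 units higher (SE 1.74, adjusted p = 0.0725). The range fit gave about the same fold with a wide SE (12.86, SE 1.9, adjusted p = 0.999, higher in 3 of 3 libraries). Over its alternatives the adjusted p ran from 2.34e-33 to 1. The TMEM30B libraries themselves lay close, at 12810, 10180 and 10250 CPM. The spread is estimated over all groups, among them the TMEM213 libraries, which held TMEM30B at 1236 and 1.882 CPM. The other genes with the smallest p were C16orf95 (-0.76, SE 0.23), RPL13P5 (1.11, SE 0.34), SLC25A18 (-1.42, SE 0.49), LINC01869 (-1.34, SE 0.47) and CCDC170 (-1.48, SE 0.55), each with an adjusted p of 1. With edgeR 0 genes passed (46 at an unadjusted p under 0.05), with DESeq2 1, with limma voom 0 and in the range fit 0.

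Empty vector against untransfected asks what transfection itself changes. Ribosomal protein genes had positive values in 49 of 50 (median 0.628, adjusted p = 0.00192 by camera), G2 and mitosis genes in 25 of 30 (median 0.544, adjusted p = 4.84e-05; ASPM 0.66). Replication-dependent histones were positive in 16 of 18 (median 1.88, adjusted p = 0.000509; H2BC5 2.1), while markers of fibroblasts were negative in 6 of 7 (median -0.813, adjusted p = 0.0336). With an estimated correlation the adjusted p was 0.995 for each, and 0 members passed, over all genes or adjusted over the list alone. The first 3 of these lists also differ between the library sets with the preset correlation, but not with an estimated one (adjusted p = 0.719 for ribosomal proteins, 0.311 for G2 and mitosis and 0.101 for histones). Fibroblast markers had an adjusted p of 0.0538 there. Both untransfected libraries belong to libraries 20 to 30 with 1 vector library, so the vector effect there rests on empty-vector replicate 3. In the range fit the ribosomal values turned (1 of 50 positive, median -0.326, adjusted p = 1.23e-09, 0.607 with an estimated correlation), G2 and mitosis genes had a median of 0.152 and histones of 0.336. The range fit called 3 genes. ZNF703, a transcriptional repressor, fell by 0.74 log2 units (SE 0.1, adjusted p = 0.0164; 242, 265 and 216 CPM with the vector against 324 and 394 CPM). UCKL1-AS1 rose by 1.71 (SE 0.26, adjusted p = 0.0344) and CDKN2AIP rose by 0.97 (SE 0.15, adjusted p = 0.0344), the last at 89.8 CPM in empty-vector replicate 3 against 40.2 and 35.3 CPM. Over their alternatives the adjusted p ran from 2.63e-08 to 0.929 for ZNF703, from 8.54e-05 to 1 for UCKL1-AS1 and from 5.66e-05 to 1 for CDKN2AIP. CDKN2AIP had 0.34 in the planned fit and -0.41 without empty-vector replicate 3. The range fit called 2328 genes without untransfected replicate 1, 23 without untransfected replicate 2, 6 without empty-vector replicate 1 and 0 without either other vector library. The genes with the smallest p were ZMYND12 (5.74, SE 1.12), SAPCD1 (-1.82, SE 0.43), HOXB-AS3 (0.95, SE 0.23), CCDC144CP (2.26, SE 0.56) and the receptor gene GPR35 (2, SE 0.52), each with an adjusted p of 0.68. ZMYND12 had 0 counts in both untransfected libraries and under 0.5 CPM with the vector. With edgeR 0 genes passed (506 at an unadjusted p under 0.05), with DESeq2 2 and with limma voom 2024. These fits have no block, so the library sets and transfection are mixed in them. With the ranges as a block limma voom called 1 gene, so at most 1 of its 2024 calls held within the ranges.

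Setting each TMEM group against the mean of the other 4 asks what is particular to 1 insert and does not use the vector libraries. TMEM30B cells stood out for HSPA5, which was the highest library of its range in all 3 ranges (558, 422 and 695 CPM). The log2 fold change was 0.78 (SE 0.23, adjusted p = 1) and, in the range fit, 0.69 (SE 0.11, adjusted p = 0.0339). TMEM72 cells stood out in the range fit for HSPA6 (4.06, SE 0.5, adjusted p = 0.0021) and HSPA1A (1.18, SE 0.15, adjusted p = 0.0021). Both genes were higher in 2 of 2 TMEM72 libraries than in the vector library of the range, which this comparison does not use. For HSPA1A in TMEM72 replicate 1 this rests on few reads (0.603 against 0.218 CPM). A library of 1 to 19 without TMEM72 held more HSPA1A, at 0.91 CPM. Of 13 fits that each left out 1 library, the HSPA6 call held in 12, all but that without TMEM72 replicate 2, the HSPA1A call in 9, and the HSPA5 call in 1, that without TMEM207 replicate 2. The HSPA1A call was lost without TMEM213 replicate 2, TMEM116 replicate 3, TMEM72 replicate 2 or TMEM30B replicate 3. In the planned fit, HSPA6 had an adjusted p of 0.117 and HSPA1A of 1. There the inserts TMEM213, TMEM116, TMEM72 and TMEM30B were each the 1 gene called in their own comparison, and TMEM207's comparison called TMEM207 and, lower, TMEM116. The test for any difference among the 6 transfected groups called 5 genes, the 5 inserts (20 genes at an unadjusted p under 0.05). In the range fit it called 7, of which HSPA5 (adjusted p = 0.0381), HSPA6 (0.00128) and HSPA1A (3.73e-05) were not inserts. Of 16 fits that each left out 1 library, HSPA5 was called in 5, HSPA6 in 14 and HSPA1A in 15; the last was lost without TMEM72 replicate 2, and HSPA6 without that library or empty-vector replicate 1. With so few genes called against empty vector, mostly the inserts, the count of calls shared between TMEM groups (0 over 10 pairs in either fit) says nothing about shared effects.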

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

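The weighing of the TMEM30B reads was chosen after they were seen; the tests of a difference between the library sets were run on all 16642 genes, with the sets themselves defined after the data were seen.

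TMEM30B reads in TMEM213 cells came from 1 library. The effect of TMEM213 on TMEM30B differed between the library sets by -9.34 log2 units (libraries 20 to 30 minus libraries 1 to 19, adjusted p = 2.97e-07 by an interaction term in edgeR), because TMEM213 replicate 1 held 19656 TMEM30B reads, or 1240 CPM, and TMEM213 replicate 2 held 1.882 CPM. Stray reads between libraries were argued against: the level was 438 times the highest of the other libraries numbered 12 to 19 that did not receive TMEM30B (2.82 CPM). Carry-over of material from TMEM30B replicate 3 was argued against as well, since 33 genes at 10 CPM or more in libraries 20 to 30 and under 0.5 CPM in the other libraries 1 to 19 reached a median of 0.024 of the level its share would need. Carry-over from TMEM30B replicate 1 or 2 and a mixed plasmid cannot be told apart, as 0 genes other than the inserts mark those libraries (10 CPM or more there, under 0.5 CPM in the other libraries 1 to 19); its TMEM30B level was 12.1% of that in TMEM30B replicate 2. The library also holds TMEM213 at 1530 CPM, and no biological explanation was tested.

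The same interaction term passed for TMEM72 and 2 heat shock genes. The difference was 1.68 log2 units for the Hsp40 gene DNAJB1 (adjusted p = 0.0243), which stood at 251 CPM in TMEM72 replicate 2 and 106 CPM in replicate 1, and 1.65 for the Hsp70 gene HSPA1B (adjusted p = 0.0243), at 768 and 523 CPM. Each set holds 1 TMEM72 library, so a difference between the sets and a difference between the 2 libraries are the same contrast here. In both these tests and that of TMEM30B, the spread (3 residual degrees of freedom) comes from other groups, and each lone TMEM72 or TMEM213 library is assumed to vary like them.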

How the results depend on the processing

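The range fit, its DESeq2, limma voom and leave-one-out forms, the block of 2 sets and libraries 1 to 19 alone were chosen after the data were seen; the other alternatives were planned. The call of TMEM116 in its own comparison against empty vector kept its direction and its side of the threshold in all 26 alternatives in which it was tested (log2 fold change 6.3 to 7.22), and the comparison's count of 1 changed in 1 of 29 alternatives, to 0 without the 5 TMEM genes. Where a count or direction below changed, the cause was not tested, except where fewer genes or libraries were used.

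Counts past the threshold in the planned fit were 0 for TMEM213, TMEM207, TMEM72 and TMEM30B against empty vector and for empty vector against untransfected. With DESeq2 they were 2 for TMEM213, 1 each for TMEM207, TMEM72 and TMEM30B, and 2 for empty vector against untransfected. With limma voom they were 1 for TMEM213, 1 for TMEM72 and 2024 for empty vector against untransfected. The replicate block gave 1 for TMEM213, 1 for TMEM207, 730 for TMEM72 and 6853 for empty vector against untransfected, and the planned library-number block 1, 1, 1 and 1324. The range fit gave 1 for TMEM213, 1 for TMEM207, 3 for TMEM72 and 3 for empty vector against untransfected. Its DESeq2 form gave 2, 1, 2 and 32, with 2 for TMEM30B, and its limma voom form 1, 1, 2 and 1. The block of 2 sets gave 1 each for TMEM213, TMEM207, TMEM72 and TMEM30B, libraries 1 to 19 alone 2, 1, 1 and 1, and only the groups of the comparison 1 for TMEM30B. Leaving out each library gave 0 to 2 for TMEM213, 0 to 1 for TMEM207, 0 to 4 for TMEM72 and 0 to 2328 for empty vector against untransfected.

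For each TMEM group against the mean of the other 4, planned counts were 1 (TMEM213), 2 (TMEM207), 1 (TMEM116), 1 (TMEM72) and 1 (TMEM30B), and the test for any difference gave 5. DESeq2 gave 3 for TMEM213, 2 for TMEM116, 3 for TMEM72 and 2 for TMEM30B; limma voom gave 2 for TMEM30B and 3 for any difference. An adjusted p under 0.01 left 1 for TMEM207. Without the low-count filter there were 1 for TMEM207, 2 for TMEM72, 2 for TMEM30B and 3 for any difference. The replicate block gave 5 for TMEM207, 2 for TMEM116, 333 for TMEM72, 4 for TMEM30B and 2316 for any difference. In the order TMEM213, TMEM207, TMEM116, TMEM72 and TMEM30B, the planned library-number block gave 3, 4, 3, 4 and 5, the range fit 3, 4, 3, 4 and 6, and libraries 1 to 19 alone 4, 4, 3, 3 and 5. The range fit with DESeq2 gave 3, 4, 3, 3 and 7, with 10 for any difference, and with limma voom 3 for TMEM213, 1 for TMEM207, 3 for TMEM116 and 5 for TMEM30B. The block of 2 sets gave 3 for TMEM72 and 2 for TMEM30B, and only the groups of the comparison 0 for TMEM207. Without the 5 TMEM genes all 5 comparisons and the test for any difference gave 0. Leaving out each library gave 0 to 4 for TMEM213, 1 to 5 for TMEM207, 1 to 3 for TMEM116, 0 to 5 for TMEM72, 0 to 5 for TMEM30B and 4 to 9 for any difference.

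Of the gene lists, 9, 2, 8, 9, 2 and 4 passed in the 6 main comparisons with the preset correlation, and 0 in each with an estimated correlation, in the planned fit and in the range fit. The planned library-number block gave 5 lists for TMEM213, the replicate block 8 for empty vector against untransfected, and the range fit 4 for TMEM207, 14 for TMEM116, 4 for TMEM30B and 8 for empty vector against untransfected. For TMEM213 the range fit lost 5 of the 9 lists. It gained lysosome and autophagy (adjusted p = 0.01 by camera), replication-dependent histones (0.01) and vacuolar ATPase subunits (0.00486), all lower and each at 0.7 with an estimated correlation.

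Directions of named genes turned mostly with untransfected cells as the control. There SAPCD1 had -0.61 with TMEM213, -0.65 with TMEM116 and -0.49 with TMEM72, and MT-CYB had -0.68 with TMEM207, -0.52 with TMEM116 and -0.26 with TMEM72. DDIT3 had 0.25 with TMEM213, IDI1 0.05 with TMEM116, RPL6 0.04 and CDK1 0.55 with TMEM72, and PDIA4 -0.07 with TMEM30B. CDKN2AIP in empty vector against untransfected had -0.32 with limma voom and -0.27 with the replicate block. Leaving out each library, MT-CYB ran from -0.2 to 0.94 with TMEM207 and from -0.03 to 1.1 with TMEM116, and NDUFA2 from -0.61 to 0.13 and from -0.64 to 0.1. With TMEM116, RPSA ran from -0.75 to 0.06 and HSPA5 from -0.59 to 0.01. HSPA1A with TMEM72 ran from -7.1 to 10.77, PDIA4 with TMEM30B from -0.01 to 0.62 and CDKN2AIP from -0.41 to 1.07. Depth limits genes of few reads: 3 counts are 0.123 CPM in the deepest library and 0.299 CPM in the shallowest.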

Other observations

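The tests of the library sets and of stray insert reads were chosen after the results were seen, as was the range fit to which the shuffled labels were applied; the other splits were planned.

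In libraries 20 to 30, the second set, most members of several gene lists were lower than in libraries 1 to 19. These lists were called only with the preset correlation. Replication-dependent histone genes were lower in the second set for 15 of 18 (median -2.09, adjusted p = 0.000151 by camera, 0.101 with an estimated correlation), among them H1-2 (17.9 ± 4.66 against 141 ± 44.3 CPM). G2 and mitosis genes were lower for 20 of 30 (adjusted p = 0.00422, 0.311 with an estimated correlation), including CDK1 (133 ± 13.2 against 285 ± 38.3 CPM). The p53 targets were lower for 14 of 20 (adjusted p = 0.0186, 0.719 with an estimated correlation), including CDKN1A (73.4 ± 3.66 against 154 ± 14.5 CPM). Higher in the second set were 2 histone genes, 2 G2 and mitosis genes and 4 p53 targets, such as BAX (91 ± 14.3 against 30 ± 4.95 CPM). In Xp22, 7 of the 11 genes between GYG2 and CLCN4 with 2 CPM or more in libraries 20 to 30 (X, 2828788 to 10237660) had under 0.1 CPM on average in libraries 1 to 19. PRKX was at 0.0425 against 40.4 CPM and SHROOM2 at 0.006 against 17.2 CPM, while TBL1X, between them, was at 53.8 against 87.7 CPM and ANOS1 at 48.2 against 2.14 CPM. In windows of 50 neighbouring genes, medians were -0.86 to -1.35 along chromosome 19 from 21496682 to 45478828, and 0.83 to 0.95 along chromosome 4 from 122923074 to 185471759.

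For the difference between the sets, a sequencing pool that follows the number ranges was argued against, since library 20 correlated across genes with libraries 21 to 30 at 0.983 to 0.996 and with libraries 12 to 19 at 0.923 to 0.936, a mean difference of 0.063 (15619 genes). GC content and transcript length were argued against as the whole cause, as they explained 2.91% of the variance. Cells of another stock with its own chromosome content may be a candidate explanation: the SD of the window medians was 0.331, 2.77 times the highest of 100 shuffled gene orders (0.12). Time in culture and the date of the experiment are not given, and no biological explanation in the design was tested.

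Low levels of TMEM213, TMEM207 and TMEM72 appear in libraries that did not receive them, and their median in a range follows the level in the library of that range that did. Stray reads between libraries of a range may explain these medians: across 7 combinations of insert and range, the median level was 0.0121 to 0.0448% of the insert library's, a ratio of 3.7 between highest and lowest. Expression of the cells' own gene that differs between the sets was tested only on TMEM207 in library 20. With 1 read (0.04105 CPM), TMEM207 there was 0.0268 of the lowest level in libraries 21 to 30, which argues against that explanation for TMEM207. The test rests on 1 library, and for TMEM213 and TMEM72 it was not run. Some single libraries depart from the medians and remain unexplained. TMEM72 was at 2.056 CPM (31 reads) in TMEM116 replicate 1, in a range without a TMEM72 library, where the other 3 libraries had 0 to 0.07501 CPM. TMEM207 was at 13.16 CPM in TMEM72 replicate 2, against a median of 2.65 CPM for its range.

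With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. As many genes as in the real split were found in 10 of 10 splits for TMEM207 against empty vector (real 0, highest other 0), 1 of 10 for TMEM116 (real 1, highest other 0) and 10 of 10 for TMEM30B (real 0, highest other 0). A real count of 0 is reached by any split, so the test cannot decide for TMEM207 and TMEM30B, and the 1 gene of TMEM116 is its insert. Beside these counts of 0 from edgeR, DESeq2 called 1 in each and limma voom 0. In edgeR, 59 genes for TMEM207 and 46 for TMEM30B had an unadjusted p under 0.05. These are far below a 0.05 share of the 16726 genes tested, so they are no sign of further changes. The planned fit has no block, so the difference between the library sets widens its spread and its p-values run high. In the range fit, shuffling the group labels within ranges gave as many genes other than the inserts in 2 of 50 arrangements, the real one included (real 3, highest other 5). That share is under 0.05, but a shuffled arrangement gave more genes than the real one, and the range fit was chosen after the data were seen. Chance as the source of the count is therefore argued against only weakly.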
